A study of Mus musculus with 6 samples.

How the data were processed

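Whole kidneys of mouse embryos at embryonic day 12.5 were profiled on Affymetrix mouse whole-genome arrays, with 3 wild-type and 3 Ret-deficient biological replicates grouped by the genotype in the sample labels. The titles and genotype fields call the embryonic kidneys Ret-deficient, while the source field gives the knockout as that of the pregnant female. The former was followed. The deposited values are MAS5 signal intensities, per the submitters' processing notes; the version, scaling target, probe masks and detection calls are not given in the sources used here. Tests on the table showed linear intensities above 0 with a mean, after trimming 2 percent at each end, of 2499 on every array, so the authors' values had been scaled to a common trimmed mean. Per the study design text RNA was amplified with a commercial kit before hybridization, while the labels' protocol describes a standard Affymetrix labelling.

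Each value was used as log2(value + 16), and differences are Ret-deficient minus wild-type. This scale understates the fold change of dim probe sets. The arrays were not normalized further because the medians of their log2 values differed by 0.42, under the limit of 0.5 set for centring. The 64 control probe sets were left out, and a probe set was tested if its mean over all 6 arrays was at or above the median of such means, which kept 22519 and left out 22518. Gene symbols came from the annotation of the array's probe sets, updated through the gene ID with RefSeq names (assembly GRCm38.p6, used for names only). Of the probe sets 34958 had 1 symbol, 932 had several and 9211 had none, and 99.42% of those with 1 symbol were updated by gene ID. Probe sets with several symbols or none were counted but not named. A gene with several tested probe sets was represented by the one with the highest mean over all arrays. No coordinates were used. Detection calls and raw probe intensities were not used here.

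The groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, no trend, no covariates), and files were read with the data.table package (version 1.17.8). P values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. The 23 gene lists were fixed in advance: ureteric bud tip, ureteric epithelium, nephron progenitor, induced nephron, renal stroma, ureteric mesenchyme and hedgehog targets, Wnt targets, FGF and ERK targets, retinoic acid, endothelium, erythroid, macrophage, neural crest and neuron, gonad, adrenal cortex, liver, skeletal muscle, cartilage, cell cycle, p53 and apoptosis, hypoxia and glycolysis, immediate early and stress, and sex-linked. Some lists share members. For each list the members that passed were counted over all tested probe sets and adjusted over the list alone. For 21 lists camera was run on the representative probe sets with a preset correlation of 0.01 and again with an estimated correlation, and fry was run beside it, each adjusted over the lists. The liver list, with 1 tested gene, and the sex-linked list were not tested as sets. Members of a list are not independent replicates. List means per array, and the 3 prime to 5 prime ratios of the control probe sets for beta-actin and Gapdh, were compared by exact two-sided permutation tests over the arrays.

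The named genes were Ret, the genes past the threshold with groups that do not overlap, at most 3 members of each list by smallest p where none passed, and all sex-linked genes. Where a direction held fewer than 5 such genes, as happened in both, the rule took the 8 with the smallest p among genes whose groups do not overlap, without clone names. The groups, tests, lists, this rule and all alternatives but 1 were fixed before the data were examined. Comparing Ret with the 27 bacterial control probe sets was decided later, as were the explanations weighed under the other observations.

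The alternatives were a pseudocount of 1 or 64, no brightness filter, a filter that kept the top 30 percent, quantile normalization, median centring, an intensity trend in the variance, array quality weights, the replicate number as a block, each array left out in turn, an adjusted p of 0.1, a minimum of 2-fold, the mean of a gene's probe sets, and an estimated correlation between genes. The bud tip list with Ret left out was added after seeing the data. The limma test was also tested on simulated data with the spread of these arrays, 22519 probe sets and 3 arrays per group, in which probe sets varied independently. It recovered 14.9% of 67 probe sets changed by 1 log2 unit, 82.1% of 67 changed by 2 and 100% of 66 changed by 4, with 9 false calls. These rates need not hold for the real arrays. There Ret, with a log2 difference of -5.43, did not pass the limma test (adjusted p = 0.51). The number of arrays limits the precision of every value.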

Results

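RNA from whole kidneys of mouse embryos at embryonic day 12.5 was measured in 2 groups, wild-type and Ret-deficient, with 3 biological replicates each and 1 array per replicate. Ret encodes the receptor through which GDNF signals to the ureteric bud, the epithelial outgrowth that branches to form the collecting system of the kidney. The comparison asks which transcripts of the kidney differ when this receptor is lacking. Of the 45101 probe sets on the array, the 22519 brightest were tested, and 11581 genes had a tested probe set with a unique symbol. The mean signal after trimming 2 percent at each end was 2499 on all 6 arrays, and the median signal lay between 258.9 and 351.6. The number of arrays limits the precision: an exact permutation test of 3 arrays against 3 cannot give a p below 0.1. The labels do not give the Ret allele, the litters or the number of embryos behind a sample.

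Ret itself was much lower in every Ret-deficient sample. Its brighter probe set, 1436359_at, read 11517 ± 1614 in wild-type kidneys and 302.4 ± 195.2 in Ret-deficient kidneys (mean signal ± SD, n = 3 per group). The fitted log2 difference was -5.43 (SE 0.53), or 43.0-fold after 16 signal units are added to each value, which is approximate because 1 of the Ret-deficient values was not above background. The 3 Ret-deficient arrays read 93.3, 479.8 and 334.1, and the lowest wild-type array read 10193. A dimmer Ret probe set, 1421359_at, fell below the brightness filter and read 631.7 ± 90.5 against 86.4 ± 21.0. The brightest bacterial control probe set, a gauge of background, read 97.2 to 186.9 on the 6 arrays, so Ret values of 479.8 and 334.1 lay above it and 93.3 did not. All 3 Ret-deficient values of the dimmer probe set (62.3, 96.2 and 100.7) lay below the brightest control of their own array (128.2, 116.8 and 133.4), so no fold change is given for it. In a limma fit without the brightness filter, adjusted over the 2 Ret probe sets alone, both had adjusted p = 6.695e-05, and the exact two-sided permutation test gave p = 0.1, its smallest value. Over all tested probe sets Ret had adjusted p = 0.51, with a range of 0.0165 to 0.998 over the alternatives. It passed the threshold with an intensity trend in the variance (adjusted p = 0.0165) and without Ret-deficient replicate 1 (log2 difference -4.78, adjusted p = 0.0266). Because the allele is unknown, neither probe set can be placed inside or outside a deleted part of the gene.

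**Figure D1:**
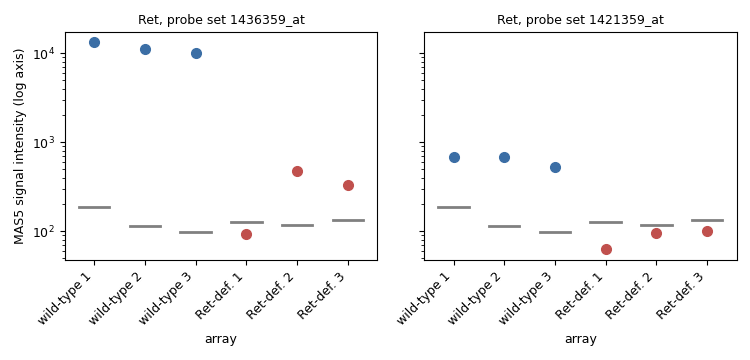
Signal of both Ret probe sets on each array, on a log axis, with wild-type arrays in blue and Ret-deficient arrays in red. Grey bars mark the brightest bacterial control probe set of the same array, and every Ret-deficient point lies below every wild-type point.

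Across the whole array no probe set passed an adjusted p of 0.05 in limma, and none passed 0.1. At an unadjusted p under 0.05 there were 1209 probe sets, 593 higher and 616 lower in Ret-deficient kidneys, where 1126 are expected by chance. Among them 260 differed at least 2-fold, 126 higher and 134 lower. The groups did not overlap at 2412 probe sets, or 10.7% of those tested, and chance gives 10%. The count of 1209 became 2140 without Ret-deficient replicate 3 and 2533 with array quality weights. It fell below the 1126 expected by chance under other alternatives. These were 838 without wild-type replicate 2, 1060 without wild-type replicate 3, 1089 without Ret-deficient replicate 2 and 1113 with an intensity trend in the variance.

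The genes with the smallest p in each direction are given as values, since none of them passed the threshold. Among those lower in Ret-deficient kidneys, Vsnl1, a neuronal calcium sensor, read 2279.9 ± 753 in wild-type and 304.4 ± 203.5 in Ret-deficient kidneys, where replicate 1 at 96.2 was not above the brightest bacterial control of 128.2, so no fold change is given. Aldh1a7, an aldehyde dehydrogenase, had -2.04 (SE 0.34) and Hs3st3a1, a heparan sulfate sulfotransferase, read 587.3 ± 102.9 against 174.7 ± 73.8, with replicate 3 at 131.9 not above its control of 133.4. Pkp2, a plakophilin of desmosomes, read 5123 ± 1429 against 1574 ± 201, a log2 difference of -1.67 (SE 0.23). The zinc finger genes Zscan10 and Zfp879 had -1.68 and -0.94. Tfap2b, a transcription factor of the ureteric epithelium list below, had -1.11 (SE 0.19). Among those higher, Islr had a log2 difference of 1.54 (SE 0.29), and Ptger4, a prostaglandin E2 receptor, read 4061 ± 299 against 11075 ± 3085, a difference of 1.41 (SE 0.22). Sncg had 1.38, the receptor tyrosine kinase gene Axl 1.23, the glutamate receptor subunit gene Grin3a 1.17 and the phosphodiesterase gene Pde1c 1.12. Inafm1 and Loxl3, a lysyl oxidase, had 0.98 and 0.96. Their adjusted p values lay between 0.8311 and 0.8389.

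Genes of the ureteric epithelium were lower in Ret-deficient kidneys as a group. All 25 tested members of this list had a negative log2 difference, with a median of -1.14, and in 9 of them the groups did not overlap. As a set they lay below the other genes (camera adjusted p = 5.26e-09; adjusted p = 0.71 with an estimated correlation). The set did not pass the fry test for a common direction (fry adjusted p = 0.768) or for changes in either direction (fry adjusted p = 0.496). No member passed the threshold over all probe sets. Adjusted over the list alone 1 gene fell, Tfap2b (log2 difference -1.11, adjusted p = 0.0163). Gata3, a transcription factor of the ureteric lineage, read 4785 ± 517 in wild-type and 2397 ± 1408 in Ret-deficient kidneys, and the tight junction gene Cldn3 read 714.5 ± 66.7 against 263.4 ± 169.1, with replicate 1 at background. The size of the difference varied between the Ret-deficient samples: against the wild-type mean the median member stood at -3.20 in replicate 1, -0.22 in replicate 2 and -0.69 in replicate 3. The wild-type arrays stood at -0.17, 0.12 and 0.09. In Ret-deficient replicate 2, 10 members lay below the lowest wild-type array and 7 above the highest, so this sample hardly showed the fall. In Ret-deficient replicate 1 the signal of 10 of the 25 members was not above the brightest bacterial control, so the median there is approximate; on the other 5 arrays this held for 0 members. Some members, chosen after their values were seen, show the extent. Cdh1, which encodes E-cadherin, read 71.7 in Ret-deficient replicate 1, 3028 and 2832 in replicates 2 and 3, and 3715 to 5361 in wild-type kidneys, the lowest of these values being at background. Calb1, which encodes calbindin and was at background there too, read 128.1 in Ret-deficient replicate 1, 13353 and 20482 in the others, and 21363 to 29916 in wild-type kidneys. Wnt9b, a signal of the ureteric epithelium to the mesenchyme, read 133.1 in Ret-deficient replicate 1 and 5066 and 2898 in the others, against 2216 to 3049 in wild-type kidneys. Without Ret-deficient replicate 1 the median of the list was -0.55, 19 of 25 members were negative, and camera gave adjusted p = 2.19e-05; without Ret-deficient replicate 2 the median was -1.99. The exact two-sided permutation test of the list mean gave p = 0.1; for the other called lists it gave p = 0.2 (bud tip and renal stroma), p = 0.3 (cell cycle and immediate early) and p = 0.4 (macrophage).

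**Figure D2:**
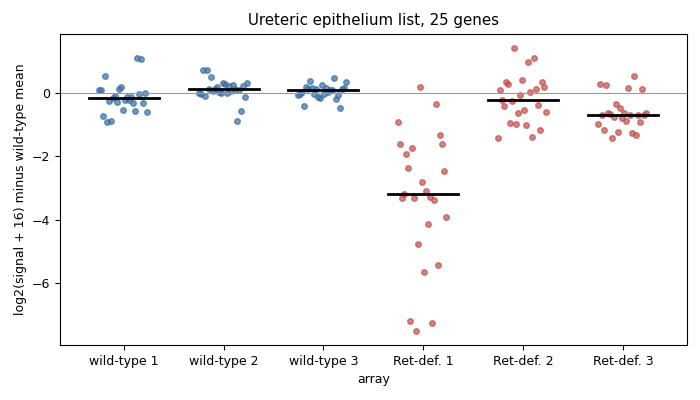
Each point is 1 of the 25 tested genes of the ureteric epithelium list on 1 array, as log2(signal + 16) minus the mean of the 3 wild-type arrays, and black bars are medians. The median was -3.20 in Ret-deficient replicate 1, where 10 genes were not above background, -0.22 in replicate 2 and -0.69 in replicate 3.

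The list of ureteric bud tip genes, many of which respond to GDNF and Ret, includes Ret itself. Of 17 tested members 13 were negative and 4 positive, with a median log2 difference of -0.29 (camera adjusted p = 0.00621; adjusted p = 0.71 with an estimated correlation). Adjusted over the list alone Ret was the 1 member that fell, and none passed over all probe sets. With Ret left out, an alternative chosen after seeing the data, the other 16 members did not pass as a set (12 negative, median -0.21, camera adjusted p = 0.0667). Those 16 passed without wild-type replicate 1 (median -0.27, adjusted p = 0.00334) but in no case with another array left out (adjusted p = 0.0767 to 0.275), with a median of -0.33 without Ret-deficient replicate 3. Against the wild-type mean the median member of the full list stood at -0.41, -0.38 and -0.0035 in Ret-deficient replicates 1, 2 and 3, and at -0.24 in wild-type replicate 1. For the full list, leaving out wild-type replicate 2 gave a median of -0.25 and adjusted p = 0.0548, and without the brightness filter adjusted p = 0.0524. Myb read 5639 ± 652 against 3919 ± 455 and Tmem59l 711.0 ± 226.8 against 211.7 ± 193.6, with replicate 1 at background. Other members, chosen after their values were seen, overlapped between the groups. Wnt11 was higher, at 470.6 ± 337.7 against 690.7 ± 96.6, with wild-type replicate 1 at background (80.7). Etv5 read 10303 ± 3689 against 8097 ± 1525 and Gfra1 3627.5 ± 797.6 against 2776 ± 930. The fry test for changes in either direction gave adjusted p = 0.0467 with Ret in the list and 0.535 with Ret left out. The fry test for a common direction gave adjusted p = 0.768 with Ret in the list and with Ret left out. Targets of FGF and ERK signalling, which share members with the tip list, had a median of -0.11 over 13 genes, with 0 past the test (camera adjusted p = 0.184, and 0.0387 with array quality weights). That median was -0.049 (adjusted p = 0.669) without wild-type replicate 2 and -0.20 (adjusted p = 0.112) without wild-type replicate 3. Among them the ETS factor gene Etv4 read 1478 ± 329 against 1013 ± 209, the feedback inhibitor gene Spry1 3805 ± 731 against 2926 ± 135 and Epha4 15777 ± 2469.9 against 13706 ± 1537.

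Among 8 targets of canonical Wnt signalling 6 were negative, with a median of -0.26 (camera adjusted p = 0.0826). Adjusted over the list alone 1 gene fell, the Wnt antagonist gene Nkd2, which read 478.4 ± 120.0 against 230.3 ± 14.7. The Wnt feedback gene Axin2 read 3363 ± 350 against 2235 ± 1185. The set passed without wild-type replicate 1 (median -0.33, adjusted p = 0.0419), without Ret-deficient replicate 2 (median -0.43, adjusted p = 0.00968) and with the mean of each gene's probe sets (adjusted p = 0.0451). Without Ret-deficient replicate 1, in turn, 4 members were negative and 4 positive, with a median of -0.095 (adjusted p = 0.598). Of 11 retinoic acid genes none passed, with a median of -0.07 and camera adjusted p = 0.495. The median was -0.17 without wild-type replicate 1, -0.12 without Ret-deficient replicate 2 and -0.016 without Ret-deficient replicate 1, none of these past the test. Within this list Aldh1a3, which makes retinoic acid, read 4823 ± 875 in wild-type and 1184 ± 728 in Ret-deficient kidneys, a log2 difference of -2.28 (SE 0.58). Aldh1a1 read 1842 ± 574 against 582.8 ± 532.3, with replicate 1 at background, and the retinol transporter gene Stra6 read 2934 ± 1059.8 against 4188 ± 452.

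The nephron progenitor genes did not pass as a set. Of 19 tested members 11 were positive and 8 negative (camera adjusted p = 0.779). Their median was 0.06 while their mean was -0.04 and camera's direction was down. With each array left out in turn the median ranged from -0.14 to 0.18. Adjusted over the list alone 1 gene fell, Gdnf, which encodes the ligand of Ret and read 3512 ± 849.8 in wild-type and 1757 ± 53 in Ret-deficient kidneys, a log2 difference of -0.97 (SE 0.21). Its adjusted p was 0.0479 over the list and 0.8668 over all probe sets. Tmem100 read 983.5 ± 205.3 against 566.0 ± 126.6 and the Wnt agonist gene Rspo1 2032 ± 415 against 3145 ± 361. Six2, a marker of the nephron progenitors chosen after its value was seen, had a log2 difference of -0.01 (SE 0.26). The list of induced nephron genes, which are switched on by Wnt signals of the ureteric bud, had a median of -0.31 over 17 members. Of these 11 were negative and none passed over all probe sets. The set did not pass (camera adjusted p = 0.0979), but passed with the replicate number as a block (camera adjusted p = 0.0324). The median of the induced nephron list was -0.13 without Ret-deficient replicate 1 or 2 and -0.20 without wild-type replicate 1. Greb1 read 5122 ± 1403 against 2148 ± 815, Itga3 2679 ± 1064 against 1418 ± 326 and Bmper 14634 ± 280 against 18840 ± 393. A dimmer probe set of Itga3 had a log2 difference of -0.03.

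Renal stroma genes were higher in Ret-deficient kidneys as a group. Of 22 tested members 16 were positive and 6 negative, with a median log2 difference of 0.28 (camera adjusted p = 0.000716; adjusted p = 0.71 with an estimated correlation), and none passed the threshold over all probe sets or adjusted over the list alone. The set did not pass the fry test for a common direction (fry adjusted p = 0.768), and the exact permutation test of the list mean gave p = 0.2. Every array was scaled to a common trimmed mean of whole-kidney RNA. A list difference, here and in the other lists, is thus relative to the rest of the RNA and does not measure an amount per kidney. The members with the smallest p were Dcn, which encodes decorin, Fbln5 and Mgp. Dcn read 317.1 ± 14.3 against 783.9 ± 313.6, Fbln5 811.2 ± 171.8 against 3219 ± 2326 and Mgp 3046 ± 1525 against 10419.6 ± 7120.2. The median of this list was 0.51 without wild-type replicate 1 and 0.15 without wild-type replicate 2. By array, its median against the wild-type mean was 0.36, 0.19 and 0.44 in Ret-deficient replicates 1, 2 and 3, and 0.16 in wild-type replicate 1. Dcn, Fbln5 and Mgp read highest in Ret-deficient replicate 3 (1142, 5777 and 18595), which also had the highest macrophage median. Of 13 genes of the ureteric mesenchyme and hedgehog signalling none passed, and their median was -0.28 (camera adjusted p = 0.6; -0.35 to 0.13 with 1 array left out). Tbx3 read 9597 ± 399.6 against 7028 ± 5358, Tbx18 6287 ± 207 against 8403 ± 2840 and Bmp4 6949.7 ± 835 against 5778 ± 1318.

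Cell cycle genes were slightly lower as a group, mostly through Ret-deficient replicate 3. Of 23 tested members 21 were negative, with a median log2 difference of -0.13 (camera adjusted p = 0.0132; adjusted p = 0.724 with an estimated correlation), and none passed over all probe sets or over the list alone. The mitotic kinase genes Plk1 and Aurkb read 6469 ± 271 against 5105 ± 762 and 6886 ± 403 against 5639 ± 411, and Bub1 14468 ± 1589 against 11676 ± 2150. Against the wild-type mean the median member stood at 0.02, -0.13 and -0.32 in Ret-deficient replicates 1, 2 and 3. In replicate 3, which also had the highest macrophage median, 20 of the 23 members lay below the lowest wild-type array, and in replicate 1 it was 5, with 7 above the highest. The call was lost without wild-type replicate 1 (median -0.05, adjusted p = 0.0837), without Ret-deficient replicate 3 (median -0.04, adjusted p = 0.534), without the brightness filter (adjusted p = 0.0981) and with array quality weights (adjusted p = 0.138), and the median was -0.20 without wild-type replicate 3. Among 11 p53 and apoptosis genes none passed (camera adjusted p = 0.779), with a median of 0.04 (-0.14 to 0.16 with 1 array left out) but a mean of -0.02 and a direction of down. Btg2 read 686.7 ± 107.5 against 1348 ± 608, Aen 8785 ± 1719 against 5904 ± 656 and Eda2r 641.7 ± 131.7 against 377.4 ± 240.1. Of 18 hypoxia and glycolysis genes none passed (camera adjusted p = 0.622), with a median of -0.04 (-0.089 to 0.026 with 1 array left out), a mean of 0.02 and a direction of down. The glycolytic gene Hk2 read 8276 ± 951 against 5663 ± 1040.3, Pdk1 10999.6 ± 1510.3 against 8199.7 ± 1422 and Vegfa 2162 ± 346 against 3071 ± 884.

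Macrophage genes were higher as a group, mostly through Ret-deficient replicate 3. All 11 tested members had a positive difference, with a median of 0.59 (camera adjusted p = 0.00621; adjusted p = 0.724 with an estimated correlation), and none passed over all probe sets or over the list alone. The complement genes C1qb and C1qc read 14880.4 ± 3534 against 24769 ± 10598 and 403.2 ± 107.7 against 921.0 ± 691.3, and the lysosomal protease gene Ctss 2704 ± 1342 against 5423 ± 3821. Against the wild-type mean the median member stood at 0.45, -0.11 and 1.45 in Ret-deficient replicates 1, 2 and 3. Without replicate 3 the median was 0.14 (adjusted p = 0.534), without wild-type replicate 2 it was 0.35 (adjusted p = 0.0548) and without Ret-deficient replicate 2 it was 0.94.

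No other list of cell types passed. The 18 endothelial genes had a median of -0.11 (camera adjusted p = 0.495), and passed without wild-type replicate 2 (median -0.29, adjusted p = 0.0145), while the median turned to 0.036 without Ret-deficient replicate 3 (adjusted p = 0.924) and was -0.0053 without wild-type replicate 1 (adjusted p = 0.638). Pecam1 read 594.2 ± 142.3 against 934.7 ± 256.3, Sox17 4448 ± 2083 against 2532 ± 835 and Cdh5 1819 ± 749.7 against 2566 ± 512. The 9 erythroid genes had a median of 0.05 (camera adjusted p = 0.649; -0.062 to 0.25 with 1 array left out), with Alas2 at 1776 ± 548 against 3797 ± 3331, Slc4a1 at 6783 ± 2959 against 11265 ± 8509 and Cpox at 3802 ± 1025 against 3085 ± 1637. A dimmer probe set of Cpox had a log2 difference of the opposite sign, 0.06. Neural crest and neuron genes had a median of -0.19 over 15 members (camera adjusted p = 0.104). In this list Sox10, a transcription factor of neural crest cells, read 4701 ± 1976 in wild-type and 1671 ± 585 in Ret-deficient kidneys, Tubb3 539.2 ± 220.3 against 244.7 ± 96.5 and Dcx 1242 ± 350 against 3589 ± 2795. That set passed without wild-type replicate 1 (median -0.44, adjusted p = 0.00362) and without Ret-deficient replicate 1 (median -0.47, adjusted p = 0.00415), but not without Ret-deficient replicate 2 (median -0.41, adjusted p = 0.0626). Its median turned to 0.11 without Ret-deficient replicate 3 (10 positive and 5 negative, adjusted p = 0.906) and was -0.0075 without wild-type replicate 3 (adjusted p = 0.746).

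Lists for neighbouring organs had few tested members, none of which passed. The 4 gonad genes had a median of -0.34 (camera adjusted p = 0.6; -0.85 to 0.21 with 1 array left out), with Wnt6 at 1442 ± 185 against 672.3 ± 703.0 (replicate 1 at background), Sycp3 at 568.9 ± 196.4 against 640.2 ± 98.1 and Amhr2 at 408.5 ± 323.9 against 300.7 ± 117.0. Wnt6 read 38.4, 1428.3 and 550.1 in Ret-deficient replicates 1, 2 and 3, lowest in replicate 1 like the ureteric epithelium list. In whole-kidney RNA the signal of a list member need not come from the organ of its list. The 4 adrenal cortex genes had a median of -0.17 (camera adjusted p = 0.621), with Mc2r at 2112 ± 699 against 1403 ± 520.2, Star at 611.0 ± 220.1 against 457.0 ± 150.7 and Fdx1 at 6736 ± 2529 against 7666 ± 1267. That median was -0.29 without Ret-deficient replicate 1, -0.058 without Ret-deficient replicate 3 and -0.078 without wild-type replicate 2. A dimmer probe set of Star had a log2 difference of the opposite sign, 0.01. Skeletal muscle genes had a median of 0.11 over 5 members (camera adjusted p = 0.947; -0.045 to 0.19 with 1 array left out), with Actc1 at 5516 ± 6666 against 4731 ± 3184, Tnnc1 at 637.3 ± 123.9 against 535.3 ± 194.8 and Tnnt1 at 516.3 ± 116.6 against 677.3 ± 328.4. For Actc1 the mean signal was lower in Ret-deficient kidneys while the log2 difference was 0.45. Cartilage genes had a median of 0.18 over 5 members (camera adjusted p = 0.779), with Col2a1 at 9618 ± 2587 against 14811 ± 8559.6, Hapln1 at 14637 ± 1747 against 12341 ± 904 and Col9a3 at 1708 ± 215 against 2052 ± 862. Their median was 0.023 without Ret-deficient replicate 1, 0.072 without wild-type replicate 1 and 0.075 without wild-type replicate 2. Of the liver list 1 gene was tested, Apoa1, which read 868.9 ± 357.4 against 875.5 ± 265.7, and 2 of its 4 probe sets had a negative log2 difference.

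Immediate early and stress genes, which tissue handling can raise, were higher in Ret-deficient replicates 1 and 2. Of 15 tested members 14 were positive, with a median log2 difference of 0.73 (camera adjusted p = 0.000716; adjusted p = 0.724 with an estimated correlation), and none passed over all probe sets or over the list alone. Egr1 read 2736 ± 995 in wild-type and 25439.6 ± 19320.4 in Ret-deficient kidneys, with 41421, 30929.5 and 3968 on the Ret-deficient arrays. Egr2, at background in wild-type replicates 1 and 3, read 128.7 ± 80.0 against 1480.2 ± 1504.5 and Jun 9179 ± 2419 against 18846 ± 7350.4. Fos, chosen after its values were seen, read 33376 and 38118 in Ret-deficient replicates 1 and 2, 405.0 in replicate 3 and at most 3027 in wild-type kidneys. Against the wild-type mean the median member stood at 1.70, 1.03 and -0.34 in Ret-deficient replicates 1, 2 and 3, and at 0.56 in wild-type replicate 1. Without Ret-deficient replicate 1 the median was 0.18 (adjusted p = 0.08), and it was 1.36 without Ret-deficient replicate 3, 1.18 without wild-type replicate 1 and 0.48 without wild-type replicate 3.

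**Figure D3:**
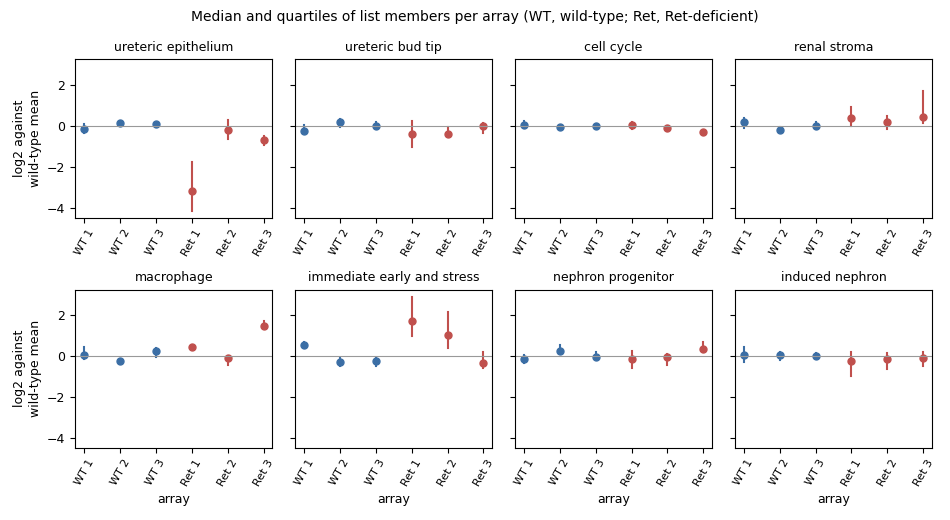
Median (point) and quartiles (line) of the tested members of 8 gene lists on each array, as log2(signal + 16) minus the mean of the 3 wild-type arrays, with wild-type (WT) in blue and Ret-deficient (Ret) in red. The ureteric epithelium list is lowest in Ret-deficient replicate 1, the macrophage list highest in Ret-deficient replicate 3, and the immediate early list highest in Ret-deficient replicates 1 and 2.

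RNA quality was uneven within the wild-type group. The ratio of the 3 prime to the 5 prime control probe set of beta-actin was 10.7 in wild-type replicate 1 and 3.88 to 5.21 on the other arrays, and that of Gapdh was 4.91 against 1.86 to 2.31. Between the groups the exact two-sided permutation test gave p = 0.6 for beta-actin and p = 0.9 for Gapdh.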

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

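All alternatives here were planned except the bud tip list with Ret left out, which was chosen after seeing the data and ended that call (median -0.21, adjusted p = 0.0667). Ret kept its direction under each one. The count of probe sets past the threshold, 0 as reported, became 1 with an intensity trend in the variance and 0 to 1 when each array was left out in turn. The call in both cases was Ret, which was lower, so the counts of genes and of lower probe sets were likewise 1. The log2 difference of Ret was -5.43 with that trend and -5.87 to -4.78 with each array left out. No probe set passed at an adjusted p of 0.1 or with a minimum of 2-fold. The fry test for a common direction, planned beside camera, passed for 0 of the 6 called lists (fry adjusted p = 0.768 to 0.812). Among them the fry test for changes in either direction passed for the bud tip list alone (fry adjusted p = 0.0467), with 0.496 to 0.796 for the others. With an estimated correlation between genes 0 of the 6 called lists kept its call. The estimates were far above the preset 0.01: 0.137 (bud tip), 0.192 (renal stroma), 0.301 (cell cycle), 0.553 (ureteric epithelium), 0.636 (immediate early) and 0.738 (macrophage). The camera p values with the preset thus treat genes that vary together as nearly independent. The median of the ureteric epithelium list was -1.14 as before (camera adjusted p = 0.709). In every other alternative that list stayed negative and past the threshold, with medians of -1.99 to -0.55. The median difference over all probe sets moved by at most 0.054. Of 1126 values for the 77 other named genes 1112 kept direction and call, and 14 changed sign without passing. Of 357 list values 308 kept both, 16 lost a call, 8 gained one and 25 changed sign; the cause was not tested.

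Without a call in either case, array quality weights turned Sycp3 (-0.12), Amhr2 (0.19), Col9a3 (-0.0095) and the medians for nephron progenitor (-0.25), ureteric mesenchyme (0.037), endothelium (0.074), gonad (0.033), p53 (-0.088) and hypoxia (0.010) genes. The top 30 percent filter turned retinoic acid (0.015), adrenal cortex (0.052) and p53 (-0.19), no filter turned p53 (-0.11), and the mean of a gene's probe sets turned retinoic acid (0.053). With each array left out in turn Amhr2 ranged from -0.57 to 0.34, Fdx1 from -0.060 to 0.51, Apoa1 from -0.18 to 0.34, Tnnt1 from -0.047 to 0.73, Actc1 from -0.79 to 1.59 and Col9a3 from -0.11 to 0.54. List medians that changed sign in this way ranged from -0.14 to 0.18 (nephron progenitor), -0.35 to 0.13 (ureteric mesenchyme), -0.29 to 0.036 (endothelium), -0.062 to 0.25 (erythroid), -0.47 to 0.11 (neural crest), -0.85 to 0.21 (gonad), -0.045 to 0.19 (skeletal muscle), -0.14 to 0.16 (p53) and -0.089 to 0.026 (hypoxia).

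With the replicate number as a block 0 probe sets passed in limma, 1141 had an unadjusted p under 0.05, and 7 lists were called in place of 6. The added list was induced nephron (median -0.31, adjusted p = 0.0324), and no other call changed. Same-numbered arrays did not deviate together from their group means (correlations of 0.03, -0.04 and -0.12). With 3 arrays per group this cannot show whether the numbers pair the samples, and the labels do not say. Signals near the background of 97.2 to 186.9, such as Ret, Vsnl1, Cdh1 and Calb1 in Ret-deficient replicate 1, bound how low a level can be read.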

Other observations

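The tests of explanations and the counts over other splits of the arrays were chosen after the results had been seen, while the sex-linked genes and the RNA ratios were planned. Sex-linked genes set wild-type replicate 1 apart. Xist, which is expressed from the inactive X chromosome, read 66.2 there and 21078 to 26277 on the other 5 arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty read 12302, 4049 and 1108 there on their brightest probe sets, and at most 67.5, 68.9 and 22.5 on the other arrays. No probe set carried the symbol Ddx3y. By Xist and the Y-linked genes wild-type replicate 1 appeared male and the other 5 arrays female, so sex was not balanced between the groups.

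Some genes of the mesenchyme and the early nephron varied widely between samples of the same group, and are given as values chosen after they were seen. Foxf1 and Foxf2, transcription factors of hedgehog-responsive mesenchyme, read 249.5 and 39.1 in Ret-deficient replicate 3, and at least 4058 and 515.3 on the other 5 arrays. The Foxf2 value of 39.1 was at background, under the brightest bacterial control of that array (133.4). Acta2, the smooth muscle actin gene, read 1815 to 28187 in wild-type kidneys. Lhx1, a transcription factor of the ureteric bud and the renal vesicle, read 5.0 in Ret-deficient replicate 1, 1113 and 1242 in replicates 2 and 3, and 2247 to 3142 in wild-type kidneys. The lowest of these values was at background too, under a brightest control of 128.2.

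The ureteric epithelium list was low above all in Ret-deficient replicate 1, whose actin, Gapdh and transferrin receptor 3 prime to 5 prime ratios were 4.25, 2.31 and 10.8. Degraded RNA is argued against by wild-type replicate 1, where all 3 ratios were higher (10.7, 4.91 and 13.6) and the list stood at -0.17 (95% bootstrap interval -0.33 to 0.00093 over members). After quantile normalization the median in Ret-deficient replicate 1 was still -3.09 (-3.26 to -1.73), which speaks against scaling. The nephron progenitor list stood at -0.15 (-0.47 to 0.19) on that array. This speaks against a shortage of metanephric tissue large enough to lower that list by 1 log2 unit, the limit used. A smaller shortage is not excluded, since 9 of the 19 members lay below the lowest wild-type array and 2 above the highest. These intervals resample list members, which are not independent, on 1 array and do not measure the spread between samples. The wild-type mean includes wild-type replicate 1, which draws the value of that array toward the mean. A genotype effect that varies between embryos, litters or dissections stays open and was not tested.

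The immediate early list was high in Ret-deficient replicates 1 and 2. Time or handling between dissection and lysis cannot be told apart from a genotype effect in part of the samples: the list's range over the wild-type arrays ranked 2 of 19 lists, neither widest nor in the lower part. The rise did not follow the size of the fall in the ureteric epithelium list. In Ret-deficient replicates 1, 2 and 3 the immediate early median was 1.70, 1.03 and -0.34, and the ureteric epithelium median -3.20, -0.22 and -0.69. Replicate 2 had the smallest fall of the epithelium list and a high immediate early median. Replicate 3 had a larger fall and no such rise. For these samples that argues against the size of that fall as the sole cause. The medians measure RNA, and the amount of epithelium was not measured. A genotype effect stays open and was not tested.

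Wild-type replicate 1 had the lowest mean Spearman correlation with the other arrays, 0.946 against at least 0.954. Without genes annotated to X or Y it was 0.9465 and still the lowest, so those genes account for little of the gap. Sex effects on other genes were not tested. RNA lacking 5 prime ends may account for the gap, since the array's actin ratio of 10.7 and its Gapdh and transferrin receptor ratios of 4.91 and 13.6 were the highest of the 6 arrays. The same array alone had low Xist and high Y-linked genes, so sex and RNA quality cannot be told apart here. No other biological difference was tested, and sex, litter or stage stay open.

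With 10 splits of the 6 arrays into groups of 3 the share of splits as large as the real one cannot fall under 0.05. For the count past the adjusted threshold the real value was 0 and the highest other 0, so all 10 splits reached it. For the count at an unadjusted p under 0.05 the real value was 1209 and the highest other 2044, and 3 of the 10 splits were as large.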
